A study of Mus musculus with 2 samples.

How the data were processed

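RNA sequencing was performed on CMT64 mouse lung carcinoma cells, with 1 library of cells transduced with GFP and 1 of cells transduced with Ascl1. Per the labels' protocols, mouse Ascl1 cDNA was carried by an MSCV-based retrovirus with neomycin resistance, G418 was used for selection, and mRNA was enriched with oligo(dT) beads, fragmented and copied with random hexamers. The extraction protocol also speaks of siRNA transfection, which no other label mentions; the groups were taken from the labelled genotype alone, and what the cells received beyond it is uncertain. The vector and selection of the GFP cells, whether the 2 cultures were grown and harvested together, and the strandedness of the libraries are not given in the sources used here. Without strand, reads of a gene and of an overlapping gene on the other strand cannot be told apart.

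The authors deposited, per library, a table of 35119 annotated transcripts with 24421 gene names, in the Ballgown transcript layout per the file headers. FPKM values in the deposited tables are fragments scaled by the authors for transcript length and for library depth, per the file headers. Coverage in the deposited tables is the mean read coverage per base of each transcript, per the file headers, and is not scaled for depth. The aligner and quantifier are not given in the sources used here. The submitters' processing notes name GRCh38, a human build, but the gene symbols and coordinates are those of mouse: of 33691 transcripts whose accession was found in a RefSeq table of GRCm38.p6, 97.16% lay on the same chromosome and inside the span of that gene. Coordinates are therefore given as in the files, as GRCm38, counted from 1.

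Depth was worked out from the tables. FPKM divided by coverage was constant within a library, which gives its total of covered bases. Among transcripts with under 1000 covered bases, coverage times length piled up at 300, 600 and 900 bases (344, 154 and 92 of 2151 in the GFP library, 366, 167 and 92 of 2360 in the Ascl1 library), so a read pair was taken as 300 bases. This gave an estimated 19.6 M pairs for the GFP library and 19.1 M for the Ascl1 library. The pairs per gene were estimated likewise, and an exact Clopper-Pearson interval at 95% of each gene's share of pairs was turned into an interval of the log2 ratio. Genes with no estimated pairs in either of the libraries got no interval. Such intervals cover counting error only, since PCR reads are not independent molecules and biological variation has no estimate.

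The FPKM of all transcripts with a gene name were summed. A gene counted as measured with an FPKM of at least 1 in either library, and the difference was log2(FPKM + 1) with Ascl1 minus that with GFP. With 1 library per group no test across replicates was possible, so genes were described by a fixed rule of size, a difference of at least 1 (2-fold). Values of exactly 0 are called listed at 0, with no claim that the gene was silent. Of 115 ribosomal, proteasome and similar genes picked by name pattern, 3 (Psma8, Psmb8 and Psmb9) were listed at 0 in either library. Psmb8 and Psmb9 also stand in the MHC class I list, so these zeros are not read as those of genes that every cell uses. For 38 gene lists the median difference of measured members was compared with 10000 random lists of the same size matched on mean expression in 20 bins. This was done where at least 5 members were measured (31 lists), and a list outside the central 95% is described as standing above or below, as a description of these libraries.

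Named genes were Ascl1, the 12 genes with the largest and the 12 with the smallest difference among genes with an FPKM of at least 5 in the higher library, up to 4 measured members of each list with the largest absolute difference, and Actb, Gapdh and Tbp. Names without an interpretable symbol and microRNA, snoRNA, ribosomal pseudogene and histone entries were left out of the 12. The lists, the rule and the alternatives were fixed before the data were examined, except where stated. The alternatives were a pseudocount of 0.1 or 5, no filter, an FPKM minimum of 5, rescaling to TPM, scaling by the median of gene ratios, the highest transcript alone, and a size of 1.5-fold or 4-fold. A minimum of covered bases, summed families and random lists matched also on GC content and transcript length were tried too, the latter pair chosen after seeing the data.

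Near-identical copies were found by aligning GENCODE M21 transcripts with BLAST+ 2.17.0 (at least 95% identity over at least 50% of the shorter transcript); gene names sharing 90% of both spans were treated as 1 locus. This gave 523 families with 1595 gene names. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data for the comparison of Ascl1 with GFP over 10908 genes. Of 50 genes each, 98.0% of those made 3-fold higher, 86.0% of those made 3-fold lower, 100.0% of those made 4-fold higher and 90.0% of those made 4-fold lower were found. Of 10708 unchanged genes, 15 passed the rule. Of 100 lists of 20 unchanged genes 2.0% lay outside the random range, and of 100 lists shifted by 0.5, 100.0% did. The simulation held counting noise only, and its lists were genes drawn independently. These rates therefore do not cover differences between dishes or lists of genes that are regulated together.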

Results

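Gene expression was measured by RNA sequencing of polyadenylated RNA in CMT64 cells, a mouse lung carcinoma line, labelled as transduced with Ascl1 or with GFP. Ascl1 is a basic helix-loop-helix transcription factor that drives neuronal and pulmonary neuroendocrine differentiation. There was 1 library per group, so no difference below has a replicate check and none has a p-value. The deposited tables gave a total of 5.87 Gb of covered bases for the GFP library and 5.72 Gb for the Ascl1 library, or an estimated 19.6 M and 19.1 M read pairs. FPKM reached 1 for 10735 genes in the GFP library and for 10930 in the Ascl1 library. Differences are Ascl1 minus GFP on the log2(FPKM + 1) scale, which understates the difference of weakly expressed genes. Counting intervals are 95% intervals of the log2 ratio of estimated read pairs, and they cover counting error only.

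The comparison asked which genes differ in expression between tumour cells carrying Ascl1 and cells carrying GFP. The transduced gene itself was listed at 0 in the GFP library and had an FPKM of 155 in the Ascl1 library, a difference of 7.29 that rested on about 6695 read pairs. Ascl1 lies on chromosome 10 at 87491041 to 87493660, on the minus strand, in GRCm38 coordinates. The tables do not separate RNA from the vector and RNA from the cells' own copy. Of 11070 measured genes, 272 were at least 2-fold higher in the Ascl1 library and 142 were at least 2-fold lower, together 3.74%. At least 4-fold differences were found for 51 genes that were higher and 14 that were lower. Over all measured genes, 88.18% differed by less than 0.5, the median difference was 0.07, and the quartiles were -0.09 and 0.21. Of the 10656 genes under 2-fold, 91.6% differed by less than 0.5. Across genes, which are not independent replicates, Pearson's r between the 2 libraries was 0.972. Of the 414 genes past 2-fold, those with an estimate of 0 read pairs in either library, such as Ascl1, had no counting interval. Among the others, 1 had a counting interval that included no difference. Adding 5 in place of 1 to each FPKM gave 95 genes higher and 62 lower, and adding 0.1 gave 405 higher and 219 lower; as TPM, 383 were higher and 172 lower.

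**Figure D1:**
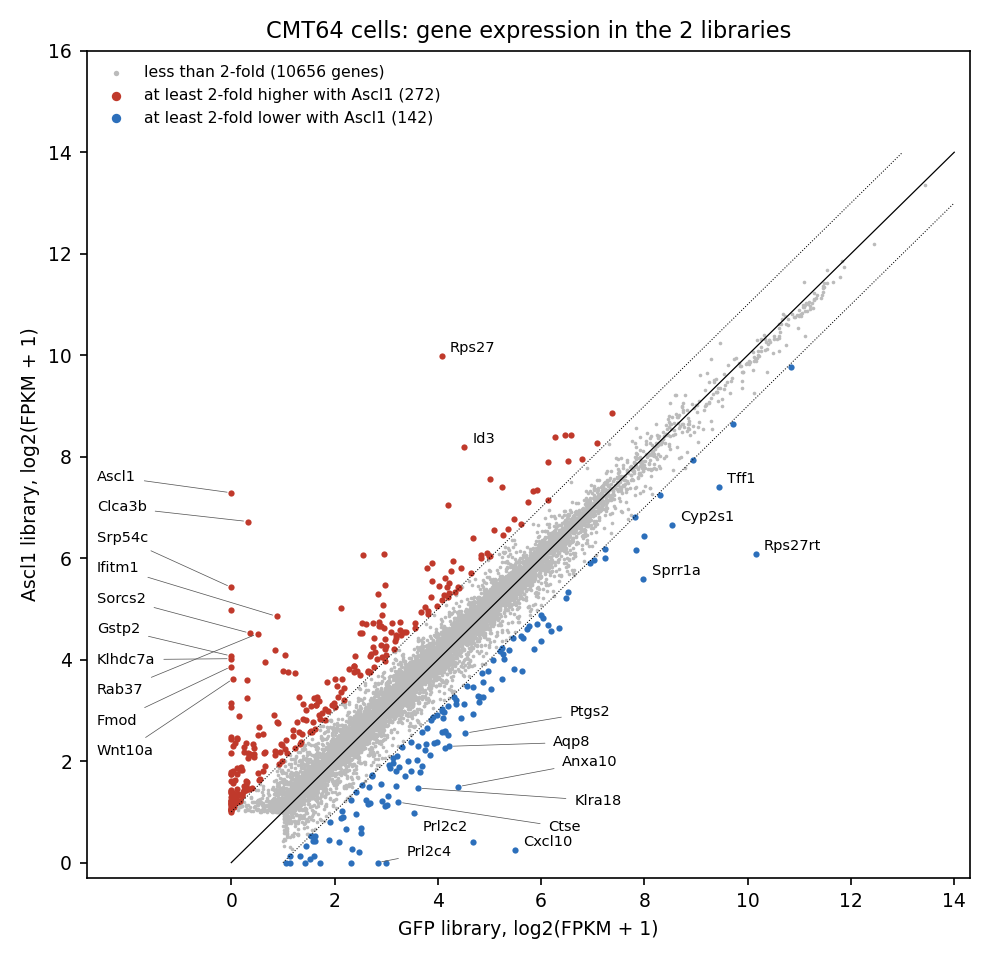
Expression of each of the 11070 measured genes in the GFP library (x axis) and the Ascl1 library (y axis), both as log2(FPKM + 1), with 1 point per gene and 1 library per axis. The solid line marks equality and the dotted lines a 2-fold difference; 272 genes lie above the upper dotted line (red) and 142 below the lower one (blue), and the named genes are those the rule took among genes with an FPKM of at least 5.

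The genes with the largest excess in the Ascl1 library, after Ascl1, included several that were at or near 0 with GFP. Clca3b, a member of the secreted calcium-activated chloride channel regulator family, had 0.246 FPKM with GFP and 105 FPKM with Ascl1, a difference of 6.405 (counting interval of the log2 ratio 8.02 to 9.53). It lies on chromosome 3 at 144822624 to 144849302. Sorcs2, a sortilin-family receptor expressed in neurons, had 0.288 FPKM with GFP and 22.0 FPKM with Ascl1 (difference 4.16). Id3, an inhibitor of basic helix-loop-helix factors, had 21.8 and 290 FPKM (difference 3.68, counting interval 3.59 to 3.89). Rab37, a small GTPase of secretory vesicles, had 0.424 and 21.8 FPKM. Ifitm1, an interferon-induced membrane protein with 1 near-identical copy in GENCODE, differed by 3.98 and the Wnt ligand Wnt10a by 3.59. Klhdc7a and Fmod, the latter a matrix proteoglycan, were listed at 0 with GFP and had 15.2 and 13.6 FPKM with Ascl1. The remaining 3 genes named by the rule, Rps27, Srp54c and Gstp2, have near-identical copies and are uncertain: Rps27 differed by 5.90, but Rps27 and Rps27rt summed differed by -0.11. The summed Srp54 family differed by 0.22 and the summed Gstp1 and Gstp2 pair by 0.09.

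Among the genes with the largest deficit, the chemokine Cxcl10, which attracts T cells and NK cells through Cxcr3, had 44.2 FPKM with GFP and 0.190 FPKM with Ascl1. This was a difference of -5.25, from about 951 and about 4 read pairs (counting interval -9.74 to -6.50). Cxcl10 lies on chromosome 5 at 92346639 to 92348889, within the span of Art3 on the other strand, and 5.9% of its exon bases overlap other genes. Anxa10, an annexin of gastric epithelium, had 20.03 and 1.82 FPKM (difference -2.90, counting interval -3.85 to -3.09). The trefoil peptide gene Tff1 had 693 and 167 FPKM (difference -2.04), Ctse, a gastric aspartic protease, differed by -2.05, and Sprr1a, a component of the cornified envelope, had 251 and 46.9 FPKM (difference -2.40). Ptgs2, the inducible cyclooxygenase, had 22.2 and 4.87 FPKM (difference -1.98). Cyp2s1, an extrahepatic cytochrome P450, had 370 and 99.1 FPKM (difference -1.89), and the water channel Aqp8 differed by -1.93. The placental prolactin-family genes Prl2c4 and Prl2c2 differed by -2.83 and -2.56; they were grouped with other Prl2c genes by sequence or locus, and that family summed differed by -3.15. Klra18 differed by -2.15, and Rps27rt, the partner of Rps27, by -4.08. Klra18 was grouped with another gene name by shared span. No GENCODE exons were found under the name Klra18, so its near-identical copies were not searched and its value is uncertain.

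Neuroendocrine and neuronal genes stayed mostly at or near 0 in both libraries. Of 28 neuroendocrine markers, 13 were listed at 0 in both libraries, among them Chga, Calca and Grp, and 7 reached an FPKM of 1 in either. Of these 7, 1 was at least 2-fold higher with Ascl1 and none was 2-fold lower. That gene was Cplx2, which regulates vesicle release and had 1.14 FPKM with Ascl1 and was listed at 0 with GFP. Insm1, a neuroendocrine transcription factor, had 0.151 and 1.18 FPKM (difference 0.92, counting interval of the log2 ratio 1.95 to 4.14), Ddc, which makes dopamine and serotonin, differed by 0.68, and Uchl1 differed by -0.48. The median of the 7 was 0.36, at percentile 94.39 of random lists of equal expression, inside their central 95%. With 0.1 in place of 1 added to FPKM, 3 of the 7 passed 2-fold higher. With 5 added 0 did, while the list median of 0.19 then lay above the random range. Among the neuronal transcription factors, 20 of 29 were listed at 0 in both libraries, including Neurod1 and Neurog2. The 4 that were measured, Hes6, Sox4, Foxa2 and Onecut2, differed by 0.42, 0.29, 0.25 and -0.20. The genes Chga, Calca, Grp, Neurod1 and Neurog2 were picked as examples after their values were seen.

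All 6 measured E proteins and Id proteins were higher with Ascl1, 2 of them at least 2-fold, and their median of 0.46 stood at percentile 99.95 of random lists. Besides Id3, Id1 had 87.0 and 345 FPKM (difference 1.97) and Id2 had 623 and 971 FPKM (difference 0.64). The E proteins differed less, Tcf4 by 0.29, Tcf12 by 0.21 and Tcf3 by 0.18. For comparison, the upper quartile of all measured genes was 0.21. In the TGF-beta and BMP pathway 14 of 21 measured genes were higher and 7 lower, 3 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.36 that lay above all 10000 random lists. Id1 and Id3 belong to this list too, and without them the median of the other 19 was 0.27, at percentile 99.94. The ligand Tgfb3 had 4.76 and 22.1 FPKM, while Ltbp1, which binds latent TGF-beta, differed by -1.06 (-0.79 with 5 added to FPKM).

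Of 20 measured genes reported as direct Ascl1 targets in other cells, 4 were at least 2-fold higher and none was 2-fold lower, and the median was 0.18, at percentile 97.61. The 4 were the Notch ligand Dll3 (difference 1.53), the corepressor Cbfa2t3 (1.10), the cell cycle phosphatase Cdc25b (1.09) and the retinal dehydrogenase Aldh1a1 (1.07). Dll3 reached only 1.96 FPKM. Gadd45g, picked after its value was seen, had 8.12 and 17.2 FPKM, just short of 2-fold on this scale, and Insm1 differed by 0.92. With 0.1 added to FPKM 6 targets passed 2-fold higher, and with 5 added 1 did. Of 15 measured Notch pathway genes, 4 were at least 2-fold higher and none was 2-fold lower: Dll3, the Notch-modifying glycosyltransferase Lfng (1.62), Dtx4 (1.19) and Notch1 (1.01). With 5 added to FPKM only Lfng still passed 2-fold. The median of the Notch list was 0.04, at percentile 28.84; it was 0.20 with an FPKM minimum of 5, also inside the random range, and below 0 at -0.02 when the libraries were scaled to a median difference near 0. Of 12 measured Wnt pathway genes, 3 were at least 2-fold higher, namely Wnt10a, the receptor Fzd2 (1.28) and the transcription factor Tcf7 (1.23, but 0.52 with 5 added to FPKM), while Wnt7a differed by -0.69. Their median of 0.22 lay at percentile 96.71, inside the central 95%. The place of the target list was lost under 6 of the alternatives tried, for example with a median of 0.12 after scaling to a median difference near 0, and the Wnt list lay above random lists with no filter on low values (median 0.21).

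Of 13 measured chemokines, 8 were lower and 5 higher in the Ascl1 library; 4 were at least 2-fold lower and none was 2-fold higher, with a median of -0.21 at percentile 0.14. Besides Cxcl10, these were Ccl5, which attracts T cells and had 2.302 FPKM with GFP and was listed at 0 with Ascl1, the dendritic cell attractant Ccl20 (difference -1.51) and the neutrophil attractant Cxcl3 (-1.08). With 5 added to FPKM only Cxcl10 still passed 2-fold, and the list median, below the random range in every setting tried, ran from -0.09 with 5 added to -0.65 with an FPKM minimum of 5. The other 13 cytokines and inflammatory mediators lay inside the random range (median -0.05, percentile 7.92; 0.00 as TPM), with 2 at least 2-fold lower, Ptgs2 and the alarmin Il33 (-1.65), and 1 at least 2-fold higher, Csf3 (1.11, but 0.33 with 5 added to FPKM). Il1rn, the interleukin-1 receptor antagonist, differed by -0.98. Of 17 measured NF-kB pathway genes, 11 were lower and 1 was at least 2-fold lower, the adhesion molecule Vcam1 (difference -1.23), with a median of -0.12 at percentile 0.34. Ier3, Relb and Tnfaip3 differed by -0.86, -0.81 and -0.80.

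Interferon-stimulated genes were mostly higher, unlike Cxcl10. Of 15 measured members, 10 were higher, with a median of 0.33 at percentile 99.79. Irf1, a transcription factor of the interferon response, had 19.99 and 42.0 FPKM (difference 1.04, but 0.91 with 5 added to FPKM and 0.97 after scaling to a median difference near 0), Igtp differed by 0.99, Isg15 by -0.72, and Oasl1 had 27.3 and 8.63 FPKM (difference -1.55). In MHC class I antigen presentation, 12 of 17 measured genes were higher and 5 lower, with a median of 0.20 at percentile 99.13. The peptide transporter Tap2 (1.38) and the immunoproteasome subunit Psmb10 (1.24) were at least 2-fold higher, but differed by 0.72 and 0.93 with 5 added to FPKM; Erap1 and Psme2 differed by 0.65 and 0.46. The class I heavy chains H2-K1 and H2-D1 and their light chain B2m, picked after their values were seen, differed by -0.25, -0.08 and 0.03. Of the class II genes only H2-DMb1 was measured (6.13 and 6.02 FPKM). Among 11 measured immune checkpoint genes and NK ligands, 6 were lower, with a median of -0.18 at percentile 0.34. Nt5e, the ectoenzyme that makes adenosine, differed by -1.07 (-0.91 with 5 added to FPKM), Cd47 by -0.66, Tnfsf9 by -0.65 and Lgals1 by 0.77. The interferon list fell inside the random range with no filter on low values (median 0.059) and with 5 added to FPKM (0.11), as did class I with an FPKM minimum of 5 (0.11) and the checkpoint list with no filter (0.015) and as TPM (0.044).

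Hypoxia and glycolysis genes were lower in the Ascl1 library almost throughout. Of 25 measured genes 24 were lower, with quartiles of -0.72 and -0.35 and a median of -0.45 that lay below all 10000 random lists. One of them, Ankrd37, passed 2-fold (38.1 and 15.2 FPKM, difference -1.27, with 26.4% of its exon bases overlapping other genes). The glycolytic enzyme Hk2 had 21.4 and 10.2 FPKM (difference -0.99), the mitophagy receptor Bnip3 had 281 and 153 FPKM (-0.88), and the glucose transporter Slc2a1 had 98.9 and 53.4 FPKM (-0.88). Genes of the unfolded protein and integrated stress response were likewise lower: 25 of 26 were lower, 2 of them at least 2-fold, and the median of -0.36 again lay below all 10000 random lists. The cystine transporter Slc7a11 had 8.16 and 1.84 FPKM (difference -1.69), Cebpb, with 20.7% of exon bases overlapping other genes, differed by -1.13, and the stress-response genes Atf3 and Trib3 differed by -0.96 and -0.95. With 5 added to FPKM neither Slc7a11 (-0.94) nor Cebpb (-0.94) passed 2-fold. The hypoxia and stress-response lists share 0 genes. Cholesterol biosynthesis genes were lower in 18 of 22 cases (median -0.20, percentile 0.02), none by 2-fold, with Pmvk at -0.61 and Stard4 at -0.52. Of 23 NRF2 antioxidant genes, 15 were lower and 3 at least 2-fold lower, namely Gsta1 (-1.76, and -1.76 with its family of 4 similar genes summed), Slc7a11 and the quinone reductase Nqo1 (-1.37), with a median of -0.14 at percentile 0.25. With 5 added to FPKM only Gsta1 still passed 2-fold. Hmox1 had 38.8 and 20.1 FPKM (difference -0.92). The 12 measured heat shock genes divided evenly, 6 higher and 6 lower (median -0.03, percentile 32.07; 0.02 as TPM), with Hspa1b at -0.64 and Dnaja1 at 0.33.

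**Figure D2:**
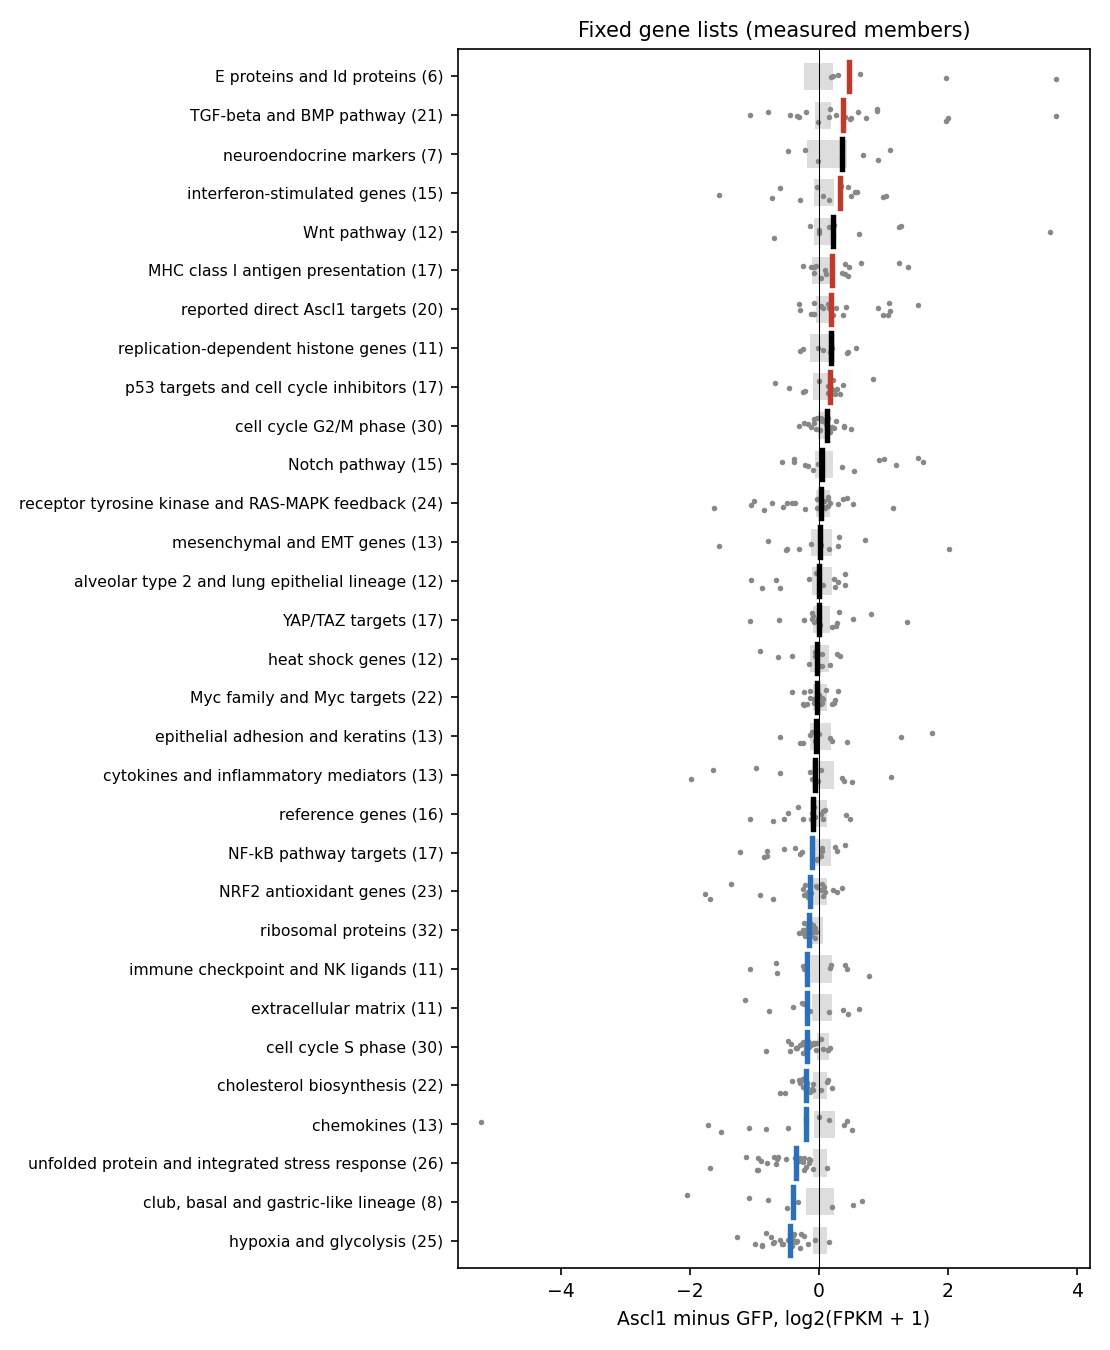
Differences between the Ascl1 and GFP libraries on the log2(FPKM + 1) scale (x axis) for the 31 gene lists with at least 5 measured members (y axis, with the number measured). Gray points are genes, vertical bars are list medians, and gray bands hold the central 95% of 10000 random lists of equal size and expression; 6 medians lie above their band (red), 11 below (blue) and 14 inside (black), from -0.45 for hypoxia and glycolysis to 0.46 for E proteins and Id proteins.

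Cell cycle genes showed small differences. All 30 S phase genes were measured, 25 were lower and none passed 2-fold, with a median of -0.19 below all 10000 random lists. Ccne2, an S phase cyclin, differed by -0.83, Gins2, with 67.3% of exon bases overlapping other genes, by -0.48, and Rrm2, a ribonucleotide reductase subunit, had 71.5 and 52.1 FPKM (difference -0.45). Of 30 G2/M genes, 22 were higher and none passed 2-fold (median 0.12, percentile 87.25, inside the random range). Ect2 and Ccnb1 differed by 0.49 and 0.38, and the survivin gene Birc5 by -0.31. Among 17 p53 targets and cell cycle inhibitors, 12 were higher and none passed 2-fold (median 0.18, percentile 99.18), with Plk2 at 0.83 and Perp at -0.69. The 22 measured genes of the Myc family and its targets had a median of -0.03 (percentile 15.43; 0.02 as TPM), and Ldha and Max differed by -0.43 and 0.29. The 11 measured genes of the histone list had a median of 0.18 (percentile 90.13), with Hist1h4i at 0.58. RNA of replication-dependent histone genes mostly lacks a poly(A) tail, so this kind of library measures such genes poorly. The list also holds H1f0 (303 and 345 FPKM) and H2afx (63.4 and 62.4 FPKM), so this need not apply to every member.

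Lineage genes gave no uniform picture. Of 8 measured genes of the club, basal and gastric-like list, 2 were at least 2-fold lower, Tff1 and the basal keratin Krt14 (difference -1.09, but -0.38 with 5 added to FPKM), and the median of -0.41 lay at percentile 0.03. Hmga2 differed by -0.79, and Sox9, a progenitor transcription factor, by 0.67. With no filter on low values this list lay inside the random range (median -0.04). The 12 measured genes of the alveolar type 2 and lung epithelial list divided evenly (median 0.01, percentile 25.24; -0.06 after scaling to a median difference near 0). Of these, only the water channel Aqp5 passed 2-fold, with 149.97 and 71.7 FPKM (-1.05). Cav1, Napsa and Muc1 differed by -0.89, -0.67 and -0.60. Among 13 epithelial adhesion and keratin genes, 2 tight junction genes were at least 2-fold higher, Cldn4 (1.75, listed at 0 with GFP) and Cldn3 (1.27), which reached only 2.36 and 1.99 FPKM with Ascl1 and lay under 2-fold with 5 added (0.56 and 0.41). Cdh1 differed by 0.43 and Elf3 by -0.61 (list median -0.05, percentile 21.60; 0.02 as TPM).

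Of 13 mesenchymal genes, the matrix glycoprotein gene Sparc had 13.8 and 58.7 FPKM (difference 2.02) and the plasminogen activator inhibitor Serpine1 had 16.6 and 4.97 FPKM (-1.56). The median of this list was 0.02 at percentile 37.02 (-0.05 after scaling to a median difference near 0). Among 11 extracellular matrix genes, 7 were lower, and the laminin chain Lamc2 was at least 2-fold lower (-1.16), with a median of -0.19 at percentile 0.31. Lamb3 differed by -0.78 and Col4a2 by 0.45. The 24 genes of receptor tyrosine kinase and RAS-MAPK feedback divided evenly, 12 each way (median 0.03, percentile 24.01; -0.04 after scaling to a median difference near 0). Of these, 3 were at least 2-fold lower, the EGFR ligand Areg (62.9 and 19.6 FPKM, difference -1.64), Phlda1 (-1.05) and Fosl1 (-1.01), and Fgfr3 was at least 2-fold higher (1.15). With 5 added to FPKM, Fosl1 (-0.64) and Fgfr3 (0.68) lay under 2-fold. For Fosl1, 57.2% of exon bases overlap other genes, so its value is uncertain. The 17 YAP/TAZ targets had a median of 0.00 at percentile 27.16, with Ankrd1 at 1.37 and Nt5e at -1.07; the median was 0.06 as TPM and -0.06 after scaling to a median difference near 0.

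Markers of other cell types were mostly at or near 0 in both libraries. Of 22 leukocyte markers, 18 were listed at 0 in both libraries and only Cd14 was measured (69.9 and 55.6 FPKM). Among fibroblast markers only Col1a1 was measured (0.306 and 1.01 FPKM) and among endothelial markers only Egfl7 (8.48 and 9.55 FPKM). Of the muscle genes, Tnnt2 (28.4 and 10.8 FPKM, difference -1.32) and Tnnc1 (-0.39) were measured. None of the 13 mitochondrially encoded genes of the list was found by name in the deposited data, so they could not be analysed.

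Genes often used as references differed by varied amounts. Actb and Tbp differed by 0.07 each, or by 0.00 each after scaling to a median difference near 0, while Ppia, which has 19 near-identical copies in GENCODE, had 1829 and 872 FPKM (difference -1.07). Gapdh differed by -0.48, and by -0.58 when summed with its near-identical copies; Pgk1 differed by -0.72 and Tfrc by -0.55. The 16 reference genes had a median of -0.09 at percentile 10.17, inside the random range. All 32 measured ribosomal protein genes were lower, none by 2-fold, with a median of -0.15 at percentile 2.24. Rpl10 differed by -0.30, Rpl3 and Rps14 by -0.25 each and Rplp0 by -0.24. The ribosomal list was inside the random range with an FPKM minimum of 5, and when random lists were matched on GC content and length as well. Altogether 31 lists were compared with random lists, which treat genes as independent although members of a list are regulated together, and 26 of the 515 measured list genes stood in more than 1 list.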

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

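Summing near-identical genes and matching random lists on GC content and length were alternatives added after seeing the data; the other alternatives were planned. Of 31 lists, 22 kept their side in every setting, and 11 of those lay outside the random range throughout. Lists kept their place in 261 of 278 combinations of list and setting, moved inside the random range in 14 and outside it in 3. Of the named genes 83 were followed: those past 2-fold, those named by rank, the reference genes and at least 1 member of each measured list. They kept their call in 465 of 499 combinations, lost it in 30, gained it in 3 and changed direction in 1. Other named genes under 2-fold, such as Insm1 (0.92) and Hk2 (-0.99), were not followed, so the count of gains is incomplete. Counts of 2-fold genes stayed within 1.5 times in 14 of 22 combinations. With a pseudocount of 0.1, 219 genes were lower; with 5, 95 were higher and 62 lower; with an FPKM minimum of 5, 165 were higher. A size of 1.5-fold gave 603 higher and 416 lower, and 4-fold gave 51 and 14, by construction. The reported Ascl1 targets lay inside with a pseudocount of 0.1 (0.19), an FPKM minimum of 5 (0.16), scaling by median of ratios (0.12), the top transcript alone (0.14), families summed (0.18) and GC and length matching (0.18). Interferon-stimulated genes lay inside with a pseudocount of 5 (0.11) or no filter (0.059). With no filter, the club, basal and gastric-like list (-0.036) and the checkpoint list (0.015) also lay inside, the latter as TPM too (0.044), and the Wnt list lay above (0.21). With an FPKM minimum of 5, MHC class I (0.11) and ribosomal proteins (-0.15) lay inside, the latter also with GC and length matching (-0.15). Neuroendocrine markers lay above with a pseudocount of 5 (0.19), and cytokines lay below with the top transcript alone (-0.12). With families summed, Rps27 turned from higher to -0.11. For the lists the cause was not tested. No paired analysis was possible because each group had 1 library, and no library could be left out. At the estimated 19.1 M and 19.6 M pairs, 1 gene past 2-fold had a counting interval including no difference, among those of the 414 with pairs in both libraries. The rest of the 414 had no interval. This count says nothing of genes that depth or the pseudocount kept below 2-fold, and the rule found 86.0% of simulated 3-fold lower genes.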

Other observations

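All patterns weighed below were seen in the data first, so every test of them was chosen after the pattern. The tests on library scaling, dish conditions, near-identical copies and interferon-stimulated genes, and the window with other chemokines included, were chosen only after the value they measure was seen. Those on GC content and length, a regional loss and counting error were set down after the pattern was seen but before their own values were computed.

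Further genes differed that stood outside the lists and the naming rule. They were picked one by one after their values were seen, and no group of them was tested. The trefoil peptide gene Tff3 had 76.2 FPKM with GFP and 333 FPKM with Ascl1 (difference 2.11, counting interval of the log2 ratio 2.01 to 2.25), while its relatives Tff1 and Tff2 differed by -2.04 and -0.32. The interferon-induced membrane protein gene Ifitm3 had 0.233 and 8.47 FPKM (2.94). Ifi27l2a and Ifi27l2b, interferon-inducible genes on chromosome 12, differed by 2.67 and 2.15, and Tmem173, which encodes the cytosolic DNA sensing adaptor STING, had 4.78 and 25.4 FPKM (2.19). The basic helix-loop-helix factor Atoh8 had 17.3 and 131 FPKM (2.85, counting interval 2.81 to 3.02), and Foxj1, the regulator of motile cilia, had 6.29 and 25.6 FPKM (1.87).

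Hmgcs2, the rate-limiting enzyme of ketone body synthesis, had 4.85 and 66.1 FPKM (3.52). The lipopolysaccharide-binding protein gene Lbp had 94.9 and 342 FPKM (1.84), and the haptoglobin gene Hp had 0.242 and 11.04 FPKM (3.28). The plasma protein genes Alb and Afp were near equality, with differences of 0.12 and -0.08. The growth factor Pdgfa had 6.74 and 66.8 FPKM (3.13), the prostaglandin D2 synthase gene Ptgds had 31.2 and 187 FPKM (2.55), and the sialomucin gene Podxl had 6.84 and 43.4 FPKM.

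Hypoxia and glycolysis genes were lower with Ascl1 in 24 of 25 cases, and so were 25 of 26 stress-response genes (median -0.36), with 0 genes in common. Library scaling moves all genes alike and is argued against, as the list median lay -0.47 from the middle of matched random lists (central range -0.12 to 0.11). The median was -0.41 as TPM and -0.52 after scaling by the median of ratios. Its percentile was 0.0 in both, which adds little, since 1 factor moves the list and the random lists together. Matching on GC content and transcript length left the list median at percentile 0.0 of random lists. A difference in density, feeding or oxygen between the dishes stays open, since with 1 library per group the dish and the vector cannot be told apart and no value in the tables decides. The hypothesis that Ascl1 itself lowers these genes is likewise untested.

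Some of the largest differences belonged to genes with near-identical copies or overlapping names. Rps27 and Rps27rt are listed over nearly the same span of chromosome 3, on the same strand. They went opposite ways, but summed they differed by -0.11. The Srp54 family summed differed by 0.22 and Gm9855 with Tdg by 0.14. A different assignment of shared reads in the 2 libraries may account for these. Gm5424, which covers the locus of Ass1, the arginine synthesis enzyme argininosuccinate synthase, was listed at 0 with GFP and had 30.4 FPKM with Ascl1. Here summing did not remove the difference: Ass1 and Gm5424 together had 0.0911 and 31.7 FPKM, a difference of 4.905. A biological difference at the Ass1 locus remains a hypothesis, since 1 library per group gives no replicate check.

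Cxcl10 had the largest deficit of the named genes (-5.25), and Ccl5 (-1.72), Ccl20 (-1.51) and Cxcl3 (-1.08) were at least 2-fold lower too, though not with 5 added to FPKM (-0.55, -0.74 and -0.79). A decline of the 15 measured interferon-stimulated genes as a whole is argued against by their median of 0.33 (bootstrap interval over members -0.03 to 0.55). That median was smaller with no filter on low values, as given above. Of the 15, 10 were higher and 5 lower, Oasl1 (-1.55) and Isg15 (-0.72) among the lower ones. A decline of part of these genes together with Cxcl10 therefore stays open. Counting error is argued against by the upper bound of the counting interval of Cxcl10, -6.50. A loss of 2-fold or more over the whole region on chromosome 5 is argued against by 26 other measured genes within 2 Mb, chemokines left out. Their median was -0.14 (-0.32 to 0.02), with Areg at least 2-fold lower and Art3 at least 2-fold higher. Over chromosome 5 genes with an FPKM of at least 5 the median was 0.07, above that interval. A smaller or partial loss of the region therefore stays open. With the other 3 measured chemokines of that window included, the 29 genes had a median of -0.16 (-0.33 to 0.00), and 2 were at least 2-fold lower, Areg and Cxcl3. A loss at Cxcl10 itself, a difference between dishes and an effect of Ascl1 on chemokines stay open, and Art3, whose span holds Cxcl10, was listed at 0 with GFP and had 4.58 FPKM with Ascl1.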
